A study of Drosophila melanogaster with 2 samples.

How the data were processed

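The series measured where CG7556, tagged with enhanced GFP, sits on chromatin in whole mixed-sex Drosophila melanogaster embryos of 0 to 24 h. It holds 2 biological replicates, numbered in the labels, of chromatin immunoprecipitation followed by sequencing with an anti-GFP antibody. Per the labels' protocols, chromatin was sheared by sonication to fragments of 200 to 800 bp. Both replicates belong to 1 group, so no test between conditions was possible, and p-values below describe peaks or genes, not animals.

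Per the deposited description files, the authors made a list of peaks and background regions from the alignments of each replicate with a control, another such list from both replicates pooled, and a list of peaks that passed IDR thresholding (the optimal list), each on builds dm6 and dm3. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The control was not analysed here, so regions that the antibody enriches without the tagged protein cannot be separated from the others by these lists beyond what the authors' own comparison did. The signal values deposited by the authors are 1 number per region on a scale that is not stated, and they were used only to rank, filter and describe regions within a list, apart from the ratio and correlation of the replicates at matched peaks. The -log10 q values deposited by the authors are saturated at the highest value of their list, 4.31 in all 7184 optimal peaks on dm6, and were not used for ranking. Summit offsets deposited by the authors give the summit as a distance from the start of the region. No p-values were used, since the deposited column holds a placeholder. Read depth per sample is unknown because the lists hold no read counts, so no interval that needs depth is given. The precision of a share is limited by the number of peaks or genes behind it.

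The dm6 lists were the basis of all results. The dm3 lists were used only for counts of regions and for the signal of mitochondrial regions, and no coordinates were converted: the optimal list held 7201 regions on dm3 and 7184 on dm6. Regions on the arms 2L, 2R, 3L, 3R, 4 and X were kept, which left out 2 mitochondrial regions of replicate 1. Genes and start sites came from Ensembl release 115 for assembly BDGP 6.54, whose coordinates are those of dm6, and sequence from the RefSeq Release 6 assembly. Every deposited dm6 region on the arms ended within the length of its reference chromosome. Transposable elements and pseudogenes were left out, leaving 13945 protein-coding and 3951 non-coding genes with 23722 start sites. Each summit was assigned in the order promoter (within 500 bp of a start site), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic.

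Replicate agreement was the share of the 7184 highest regions of replicate 1 that overlapped by at least 1 bp any of the 7184 highest of replicate 2, compared with 1000 circular shifts. The background for the other peak tests was the 19876 pooled regions that overlapped no optimal peak, because those could have passed the authors' threshold. Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 27 motifs or the 34 gene lists and a threshold of 0.05. Differences of medians were tested by permutation with 100000 resamples for signal and 10000 for GC content. Motifs were counted on either strand in windows reaching 100 bp to either side of the summit. Hexamers with their reverse complements merged had to pass a Bonferroni-adjusted p of 0.05 in Fisher's exact test with an odds ratio above 1.5, first on 2L, 2R and X and then on 3L, 3R and 4. Core promoter elements were counted in the window from 100 bp upstream to 50 bp downstream of the 5'-most start site of each protein-coding gene, and a promoter was bound there when an optimal summit lay within 500 bp of that start site. In the gene lists a gene was called bound when an optimal summit lay within 500 bp of any of its start sites, and each list was compared with the other protein-coding genes or, for RNA genes, the other non-coding genes. A summit could therefore count for several genes, also where the nearest start site was that of another gene.

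The gene lists, the motifs, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. Older symbols in the lists were matched to current ones, and none was left unmatched. The named genes are those with the start site nearest to the 10 peaks of highest signal, those nearest to the 5 highest peaks more than 2000 bp from a start site, the tagged gene, and the bound members with the highest signal of each list, up to 4 for a list that was higher, 3 for one that was lower and 2 for any other. The text also names neighbours that span a named summit. The alternatives were each replicate alone, the 3592 strongest optimal peaks, other overlap rules, other windows, other backgrounds, matching on GC content, and thinning of clustered genes. Merging of overlapping regions and assignment to the nearest start site only were added after seeing the data.

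The scripts were tested on simulated data. Overlaps of 400 regions matched a direct comparison in all 400 cases. Sequences planted in 5% of mock peaks were called in 3 of 3 cases, and of 24 that were not planted 1 was called, a part of a planted sequence. A random split gave 0 calls of 27 motifs and 0 hexamers that passed on both sets of arms. Gene lists raised 3 times were called in 60 of 60 cases, and of 620 tests on lists that were not raised 1 was called. The raised lists had 91, 73 and 179 members, and every gene was drawn independently. The simulation therefore does not show the power for small lists or smaller differences, or the error rate where neighbours share summits. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.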

Results

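Chromatin from whole Drosophila melanogaster embryos of both sexes, collected 0 to 24 h after egg laying, was immunoprecipitated with an antibody against GFP. The flies carried a transgene that makes the protein encoded by CG7556 with GFP at its C-terminal end, so peaks are meant to mark where the tagged protein was held on chromatin. The control was not analysed here, so regions that the antibody enriches without the tagged protein may be among them. Bound below means only that an optimal peak was present. The 2 samples were biological replicates of this single group, and the labels name no second condition. The comparisons were therefore between the replicates, between the peaks the authors accepted and the weaker regions they did not, and between classes of genes. Each replicate contributed a list of 30000 regions, and the pooled reads gave another 30000. The authors' reproducibility step (irreproducible discovery rate, IDR) then kept 7184 peaks, here called the optimal peaks. These fell into 6125 separate stretches after merging of overlaps, covered 2.80 Mb and had a median width of 502 bp. Their signal, the authors' value per peak on a scale that the sources used here do not state, ran from 137 to 4859 with a median of 244. Read depth is unknown, because the lists hold no read counts. Coordinates are 1-based positions of build dm6.

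The regions of highest signal largely coincided between the replicates. The 5 peaks with the highest signal, at cbt, CG11050, px, lncRNA:CR44619 and Trl, held ranks 1 to 5 in the same order in both replicate lists on the 6 chromosome arms. Of the 7184 regions with the highest signal in replicate 1, 6112 (85.1%) overlapped a region of equal standing in replicate 2 by at least 1 bp. When replicate 2 was shifted along each chromosome 1000 times, the mean overlap was 4.24% and the highest 5.19% (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). With all listed regions on the arms, background included, the overlap was 80.4% (24131 of 29998), against a shift mean of 17.5%. High overlap was therefore not particular to the highest regions, and the shifts do not show that it comes from the tagged protein. Of the 100 highest regions of replicate 1, 92 overlapped one of the 100 highest of replicate 2.

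Over the 6771 optimal peaks with a summit within 100 bp in both replicates, the 2 signals ranked alike, with a Spearman rho of 0.80 and a Pearson r of 0.85 on log2 values. These are correlations across peaks, which are not independent replicates. The median ratio of replicate 1 to replicate 2 was 1.08, with a 5th percentile of 0.565 and a 95th percentile of 1.70. Weak peaks appeared to spread more than strong ones in the plot of replicate signals, but the spread was not measured by signal. The optimal peaks were exactly the 7184 pooled regions with the highest signal, since the lowest optimal value was 137.112 and the next pooled region had 137.102. Of them, 62 were among the 7184 highest regions of neither replicate.

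**Figure D1:**
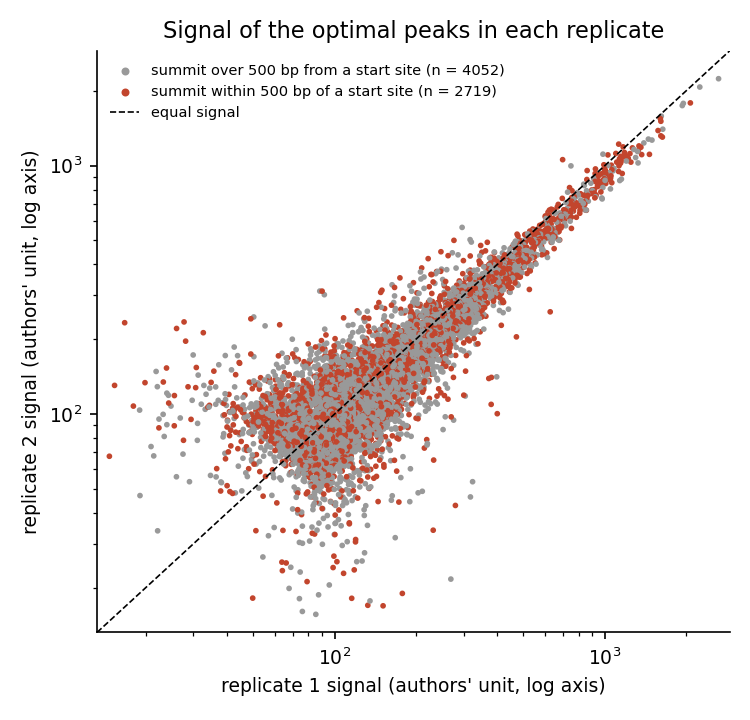
Signal of each optimal peak in replicate 1 (x axis) and replicate 2 (y axis), in the authors' unit on log axes, for the 6771 peaks with a summit within 100 bp in both; red points have a summit within 500 bp of a start site, grey points do not, and the dashed line marks equal signal. The points lie along the line with a Spearman rho of 0.80, and the highest peak, near cbt, is highest in both replicates.

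Optimal summits lay most often at promoters and in introns, and hardly ever in coding exons away from promoters. A summit lay within 500 bp of an annotated transcription start site in 2915 of 7184 optimal peaks (40.6%). Among 19876 sub-threshold regions, the pooled regions that overlap no optimal peak, the share was 25.5%, and among 7184 random positions on the same chromosomes it was 13.3%. The odds ratio of optimal against sub-threshold was 1.99 (Fisher's exact test, two-sided, p = 2.09e-122). Introns held 2863 further summits (39.9%, against 47.1% of sub-threshold regions), and intergenic sequence held 1229 (17.1% against 22.3%). Of random positions 38.9% fell in introns and 27.7% in intergenic sequence, so the intron share was close to that of random positions. Only 11 summits (0.153%) fell in coding exons more than 500 bp from every start site, where 1.17% of sub-threshold regions and 14.0% of random positions fell. Coding exons within 500 bp of a start site count as promoter here. The 3' UTR share was likewise lower, at 0.780% against 2.08%. Summits more than 2000 bp from every start site made up 35.9% of optimal peaks and 51.5% of sub-threshold regions. These tests describe the lists, since peaks and not animals are their units.

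**Figure D2:**
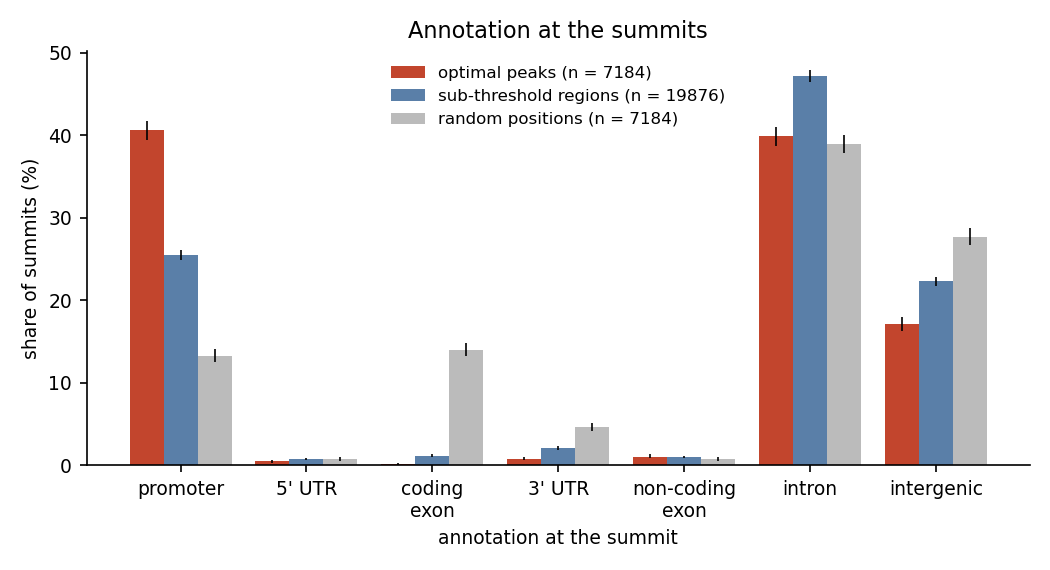
Share of summits (y axis, %) in each annotation class (x axis) for optimal peaks, sub-threshold regions and random positions; bars show the share and lines its 95% Wilson interval, which covers counting error only. Promoters hold 40.6% of optimal summits against 25.5% of sub-threshold ones, and coding exons outside promoters hold 0.153% against 1.17%.

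The peak with the highest signal, on 2L from 479614 to 481568 with a value of 4859, had its summit at 481101, which is 1413 bp upstream of cbt, a zinc-finger transcription factor gene, and inside an intron of ush, which encodes a cofactor of GATA factors. CG11050 carried the next (signal 4298), in its own intron 1017 bp downstream of a start site on 2L. The peak of px (signal 3850), a wing vein gene on 2R, had its summit at 22514301, 202 bp upstream of a start site within the gene's span. On X, a summit at 12751327 (signal 3755) lay 540 bp upstream of lncRNA:CR44619 in an exon of lncRNA:Vinr. Trl, which encodes the GAGA factor, held a peak (signal 3673) in an intron 1532 bp downstream of a start site on 3L, with its summit at 14759517. The high mobility group genes HmgD and HmgZ shared an intronic summit at 21703390 on 2R (signal 3192). CG31145, Ugalt (a UDP-galactose transporter gene) and CG14100 had promoter peaks with signals of 3139, 3117 and 2957, at 198, 40 and 96 bp upstream of their start sites. The ninth peak by signal (3022) stood alone in intergenic sequence of 2R at 13035338, 11918 bp from the nearest start site, that of CG13323.

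Beyond 2000 bp from any start site, that intergenic 2R peak was the strongest. It was followed by an intergenic peak on 2L at 1638778 (signal 2625), 8385 bp from lncRNA:CR45695. Next came intronic peaks in Tlk, which encodes the Tousled-like kinase (X, 3742225, signal 2445), and in simj, with CG11811 as the nearest start site at 8049 bp (3L, 10682975, signal 2434). An intronic peak in Kdm2, a histone demethylase gene, was at 9057557 on 3R (signal 2344). Their ranks over all optimal peaks ran from 9 to 28, and Kdm2 ranked 21 in replicate 1 and 45 in replicate 2.

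The tagged gene itself carried a peak. CG7556 (FBgn0030990) lies on the minus strand of X from 19176109 to 19179830. The optimal peak from 19179734 to 19180261 had its summit at 19180000, 170 bp upstream of the CG7556 start site, with a signal of 756 and rank 574 of 7184. The corresponding regions ranked 489 in replicate 1 and 721 in replicate 2. This is intergenic sequence between CG7556 and CG7453 (19180173 to 19182024, plus strand), which are transcribed away from each other. A second summit in the same region, at 19180200, lay 27 bp inside the 5' UTR of CG7453 with a signal of 298 (rank 2733). Within the gene body, replicate 2 alone listed a region, in the 3' UTR at 19176492, with a signal of 16.2 and rank 29149 of 30000. A transgene can add copies of its own locus, so the signal there is not comparable with that of other promoters.

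At promoters the summits lay upstream of the start site. Among 1907 promoter summits without start sites on both strands within 500 bp, the median position was -175 bp, with quartiles of -300 and -39.5 bp. Upstream summits numbered 1525 and downstream ones 380 (19.9%; exact two-sided binomial test, p = 5.22e-162). Sub-threshold regions at promoters sat closer to the start site, with a median of -31 bp and 45.0% downstream. The 3592 optimal peaks with the highest signal had a median of -203 bp. Restricting the window to 200 bp on either side moved the median to -91 bp, which the narrower window itself limits.

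**Figure D3:**
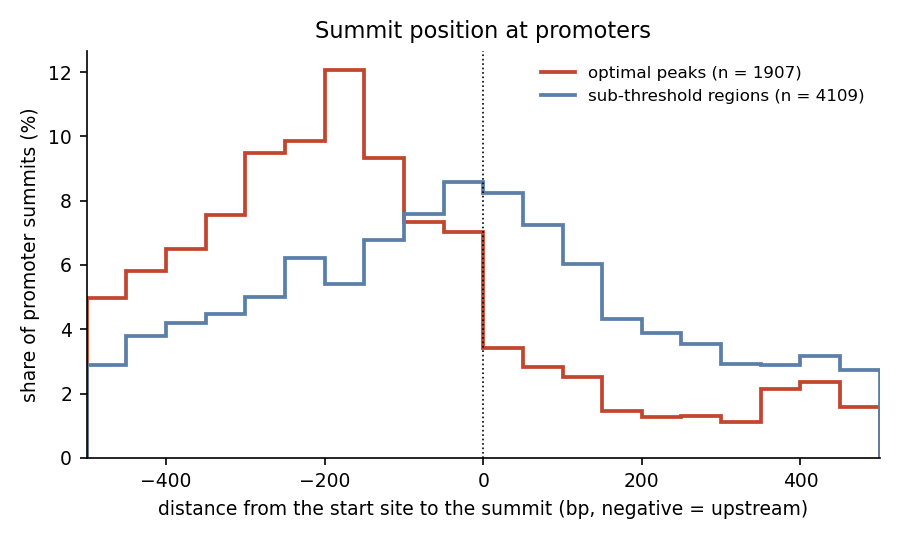
Position of promoter summits relative to the nearest start site (x axis, bp, negative is upstream) as a share of summits in bins of 50 bp (y axis, %), for 1907 optimal peaks and 4109 sub-threshold regions. Optimal summits are most frequent from 200 to 150 bp upstream, where the bin holds 12.1% of them against 5.40% of sub-threshold summits.

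Promoter peaks were somewhat stronger than distal ones. The median signal was 272 at 2915 promoter peaks and 223 at 2581 peaks more than 2000 bp from a start site, a ratio of 1.22 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). With the replicates taken singly, the ratio was 1.24 for replicate 1 and 1.15 for replicate 2.

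Optimal peaks were spread over the large chromosome arms, and chromosome 4 had few. The X carried 57.3 optimal peaks per Mb, 3L 56.9, 2L 56.0, 3R 52.0, 2R 48.9 and chromosome 4 only 9.64 (13 peaks). Sub-threshold regions were also few on chromosome 4, at 34.1 per Mb against 136 to 172 on the other arms. Protein-coding genes were sparser there too (59.3 per Mb against 93.3 to 113), with 0.163 optimal peaks per such gene against 0.434 to 0.614. The X held 1349 of 7171 peaks on the X and the arms of chromosomes 2 and 3 (18.8%), against 20.4% of sub-threshold regions (odds ratio 0.902, Fisher's exact test, p = 0.00323). Against chromosome length, which gives 17.8%, the direction was the opposite (odds ratio 1.07, exact binomial test, p = 0.0213). The X share was therefore lower or higher according to the background chosen.

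Genes of the ribosome stood out among the gene lists. Of 91 cytoplasmic ribosomal protein genes, 59 (64.8%, 95% exact interval 54.1% to 74.6%) had an optimal summit within 500 bp of a start site, against 20.8% of the other protein-coding genes (odds ratio 7.03, Fisher's exact test, adjusted p = 6.80e-18). Mitochondrial ribosomal protein genes followed with 25 of 73 (34.2% against 21.0%, adjusted p = 0.0435, Fisher's exact test). Long non-coding RNA genes were bound in 187 of 1944 cases (9.62%), against 6.53% of the other non-coding genes (Fisher's exact test, adjusted p = 0.00242). The highest ribosomal protein peaks were those of RpL7 (signal 833), RpS27 (823), RpL34b (776) and RpL14 (627), all within 147 bp of a start site and ranked from 477 to 818. The mitochondrial list reached higher signals, with 2218 at mRpS10, 2002 at mRpL41, 1782 at mRpS23 and 1516 at mRpL23. Among the long non-coding RNAs the highest were lncRNA:CR44339 (2934), lncRNA:CR46036 (2479), lncRNA:CR44120 (2147) and lncRNA:CR44149 (2081). At mRpS10 and mRpS23 the summits lay 134 and 397 bp from a start site of the gene, but the nearest start site was another gene's. The same held for RpL34b and lncRNA:CR44120, so these signals may belong to neighbours.

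Chemosensory receptor, cuticle protein, histone and microRNA genes were bound less often than other genes of their class. Chemosensory receptor genes had 1 bound member of 179 (0.559%), Or88a with a signal of 207, against 21.3% of the other genes (Fisher's exact test, adjusted p = 4.66e-16). Cuticle protein genes had 1 of 70 (1.43%), Cpr67Fb with a signal of 250 (adjusted p = 1.87e-05, Fisher's exact test). None of 111 replication-dependent histone genes was bound, with an adjusted p of 5.71e-11 (Fisher's exact test) when each gene is counted singly. These genes lie in a repeat array, and with 1 gene kept per cluster 2 members remained, 0 of them bound, and the call ended (Fisher's exact test, adjusted p = 1). No histone gene had a pooled region of any strength within 500 bp. The histone count is uncertain, because these genes are near-identical copies and how the authors treated reads that match several copies is not given in the sources used here. MicroRNA genes had 10 bound members of 260 (3.85% against 8.34%, Fisher's exact test, adjusted p = 0.0435), led by mir-9377 (669), mir-9378 (545) and mir-2496 (459). The start site nearest to each of these summits was that of another gene. Annotated microRNA genes can be short, mir-9377 running from 12665217 to 12665268, and their annotated starts may not be promoters. The microRNA and long non-coding RNA lists each form part of the other's comparison group. Their calls are thus not independent, and differences in how start sites are annotated were not tested.

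The ribosomal protein result passed under all 9 other settings. The mitochondrial ribosomal call passed under 4 of 9 and was lost, for example, when each summit was given only to its nearest start site, a setting chosen after seeing the data (15 of 73, 20.5% against 15.9%, Fisher's exact test, adjusted p = 0.446). The long non-coding RNA call passed under 5 of 9 and ended without replicate 1 (9.21% against 7.22%, Fisher's exact test, adjusted p = 0.0808) and with 1 gene per cluster (9.08% against 7.50%, Fisher's exact test, adjusted p = 0.264). The microRNA call passed under 3 of 9, and without replicate 1 the difference was of similar size but did not pass (4.23% against 8.48%, Fisher's exact test, adjusted p = 0.0578). When the comparison was limited to genes with any pooled region within 500 bp, the chemosensory, cuticle and histone calls ended, with 7, 8 and 0 members left to test. Of these, 1 chemosensory and 1 cuticle gene were bound, so the lost calls rest on few genes. Over all 34 lists, 3 were higher, 4 were lower and the rest did not pass. Neighbouring genes share promoters and are not independent.

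Of all protein-coding genes, 2939 of 13945 (21.1%) were bound, and the lists that follow did not pass the test by default. Insulator and promoter-binding proteins had 9 bound of 20, including Chro (signal 2239) and Cp190 (1466). Endoplasmic reticulum chaperone and stress genes had 11 of 26, including Hrd3 (2116) and CG7556 itself. CG7556 had been placed in that list from memory of its annotation, while RefSeq calls it uncharacterized, and a transgene can add copies of its locus. The list was called higher with the 200 bp definition of bound, with the 5'-most start site only and with the nearest start site only. It was not tested without CG7556, so its share and these calls carry this limit. DNA replication and cell cycle genes had 13 of 33, with CycE (1071) and Dp (564) highest. Translation factors had 18 of 53, with eIF4EHP (1974) and eIF6 (1374), and heat shock and cytosolic chaperone genes 9 of 24, with Hsp27 (1330) and mrj (1150). Adjusted p-values of these 5 lists ran from 0.0588 to 0.157 in Fisher's exact test. The insulator and translation factor lists were called higher with the 200 bp definition of bound and without replicate 1. Oxidative phosphorylation genes had 19 of 77 bound (ND-ASHI 858, ND-42 530), proteasome genes 8 of 32 (Rpn5 530, Rpn3 428) and Polycomb and trithorax genes 6 of 28 (ph-p 1340, brm 920). For eIF4EHP, eIF6, ND-ASHI, ND-42, Rpn5 and brm the start site nearest to the summit was another gene's, so these signals may belong to neighbours.

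Developmental regulators with a strong peak within 500 bp of a start site included elav, E(spl)m3-HLH, trh and tin, but no list of them passed the test. The summits counted for elav and E(spl)m3-HLH lay 264 and 416 bp upstream of these genes. In both cases the nearest start site was that of another gene, and the elav summit fell in another gene's intron. Enhancer of split and Notch pathway genes had 7 of 19 bound, led by E(spl)m3-HLH (1805) and E(spl)m7-HLH (1248), which encode repressors induced by Notch. Only Antp (224) was bound of 8 Hox genes, tin (941) of 18 dorsoventral genes, and fkh (785) of 20 gut and Malpighian tubule genes. Of the 20 members of the gap and pair-rule list only bcd (169) was bound, which is itself a maternal gene. Segment polarity genes had 3 of 12 (nkd 630, fz 151), and neuroblast and proneural genes 5 of 20 (grh 335, nerfin-1 321). Neuronal differentiation genes had 2 of 19, namely elav (1904), a pan-neuronal RNA-binding protein gene, and fne (250). Glial genes had 3 of 10 (moody 1118, Gli 459), muscle genes 7 of 29 (sls 555, Tm1 531), epidermal and tracheal genes 5 of 18 (trh 1494, grh again) and germline genes 6 of 18 (stwl 514, gcl 418). For grh and gcl too, the start site nearest to the summit was another gene's. No gene was bound of 14 for fat body and hemocytes, 18 for antimicrobial peptides, 15 for eggshell proteins, or 15 for yolk and odorant-binding proteins. Of the small RNA classes, 25 of 290 tRNA genes, 17 of 274 snoRNA genes and 2 of 32 snRNA genes were bound, led by tRNA:Tyr-GTA-1-8 (1538), snoRNA:U49:66Da (627, the RpL14 peak) and snRNA:U5:63BC (151). None of these lists passed the test.

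**Figure D4:**
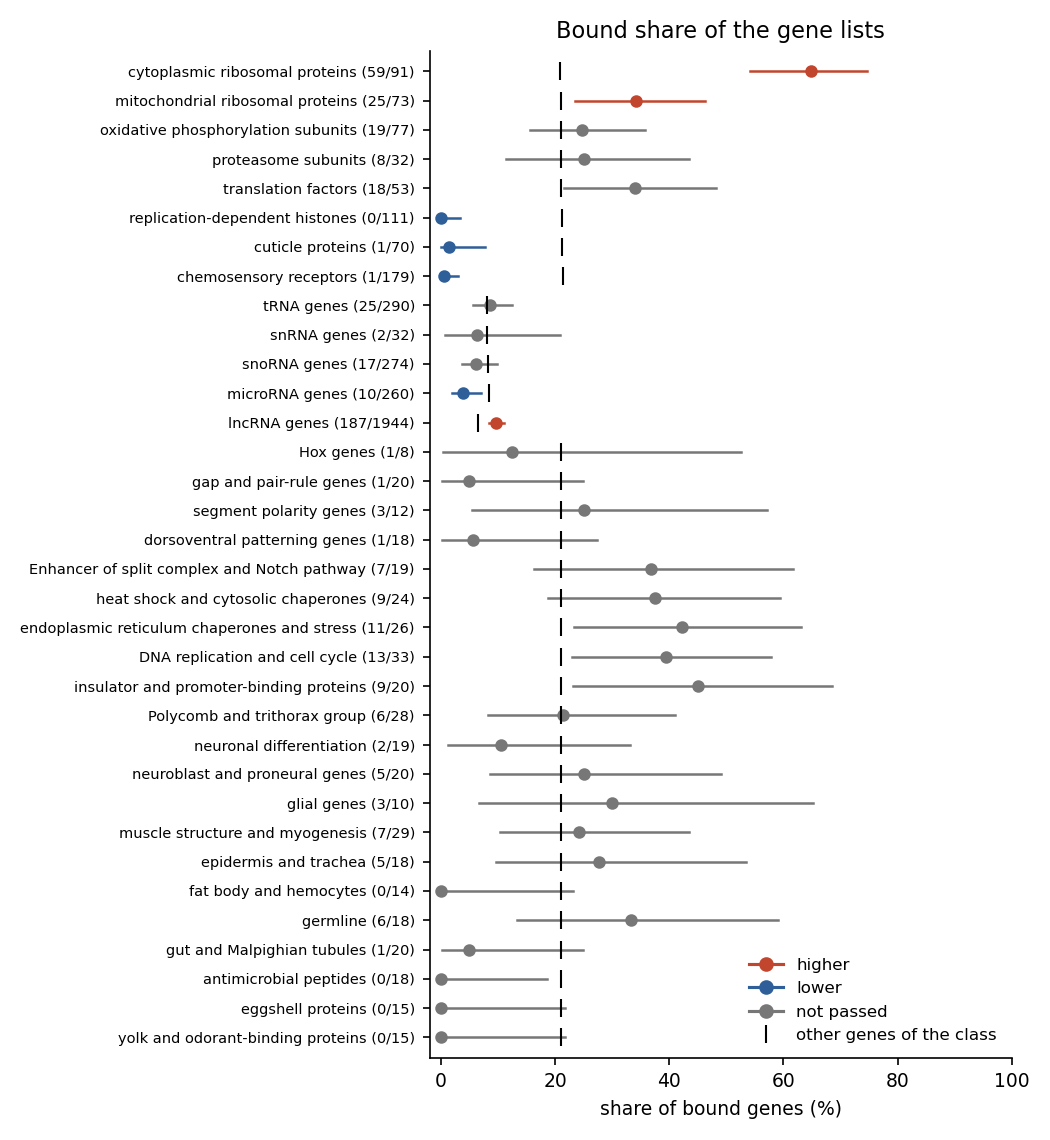
Share of genes bound (x axis, %, an optimal summit within 500 bp of a start site) for the 34 gene lists (y axis, bound and total members in brackets); points show the share, horizontal lines its exact 95% interval and vertical ticks the share among the other genes of the same class. Cytoplasmic ribosomal protein genes stand at 64.8%, far above the 20.8% of other genes, and chemosensory receptor genes at 0.559%.

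Compared with all other protein-coding promoters, bound ones more often carried Ohler motif 7, the E-box CAGCTG and the DNA replication-related element (DRE). They less often carried an initiator or a TATA box. Ohler motif 7, DRE and Motif 1 are known from promoters of broadly used genes, and the TATA box from regulated ones. Ohler motif 7 was present in 24.0% of 2577 bound promoters and in 11.6% of 11368 others, from 100 bp upstream to 50 bp downstream of the start site (odds ratio 2.40, Fisher's exact test, adjusted p = 2.05e-52). Bound here means an optimal summit within 500 bp of the 5'-most start site, so the others include genes bound only at another start site. They also include promoters with only a sub-threshold region and promoters with no pooled region. The CAGCTG E-box (17.2% against 10.9%, odds ratio 1.69), DRE (TATCGATA, 10.9% against 6.90%, odds ratio 1.65), CGATA (41.7% against 32.8%, odds ratio 1.47) and Motif 1 (8.46% against 6.18%, odds ratio 1.40) were also higher. Every promoter with DRE also counts as one with CGATA, so their calls are not independent. The initiator was lower, at 18.3% against 27.3% (odds ratio 0.598, Fisher's exact test, adjusted p = 6.62e-21), and so was the TATA box, at 7.45% of bound promoters (odds ratio 0.541, adjusted p = 2.04e-15 in the same test). In all, 7 of 27 sequences were higher and 4 lower, and the other members were CACGTG and the GAGA element on the higher side and the TCF and Zelda sites on the lower. With unbound promoters matched on GC content, which cut their number to 2577, those last 4 did not pass, leaving 5 higher and 2 lower. Of the 4, only the GAGA element lost most of its difference (odds ratio 1.16 to 1.03), while the ratios went from 0.603 to 0.611 for TCF, from 0.488 to 0.548 for Zelda and from 1.54 to 1.35 for CACGTG. The smaller background also lowers the power of the test. The GAGA call also ended without replicate 2 and, with an odds ratio of 0.910, with the 200 bp definition of bound, and the Motif 1 call ended at the stricter threshold (odds ratio 1.08). The Zelda site did not pass without replicate 1, at a similar odds ratio of 0.514 (Fisher's exact test, adjusted p = 0.0502). At the stricter threshold the Zelda, TCF and CACGTG calls ended too, with odds ratios of 0.713, 0.785 and 1.33. The TCF call also ended with the 200 bp definition of bound (0.730).

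The sequence under the summits was poor in G and C. Median GC content in windows reaching 100 bp to either side was 33.3% at optimal summits, 38.3% at sub-threshold summits and 41.8% at random positions, and the difference of -4.98 percentage points between the first 2 was beyond all 10000 permutations (two-sided permutation p = 1e-04, the smallest they can give). Promoter summits differed most, by -6.97 points. Optimal summits there also lay further upstream than sub-threshold ones (medians of -175 and -31 bp without start sites on both strands). GC content was not compared at equal distance from the start site. At 400 to 600 bp from the summit, mean GC content was instead higher around optimal peaks, at 44.0% against 43.1%.

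**Figure D5:**
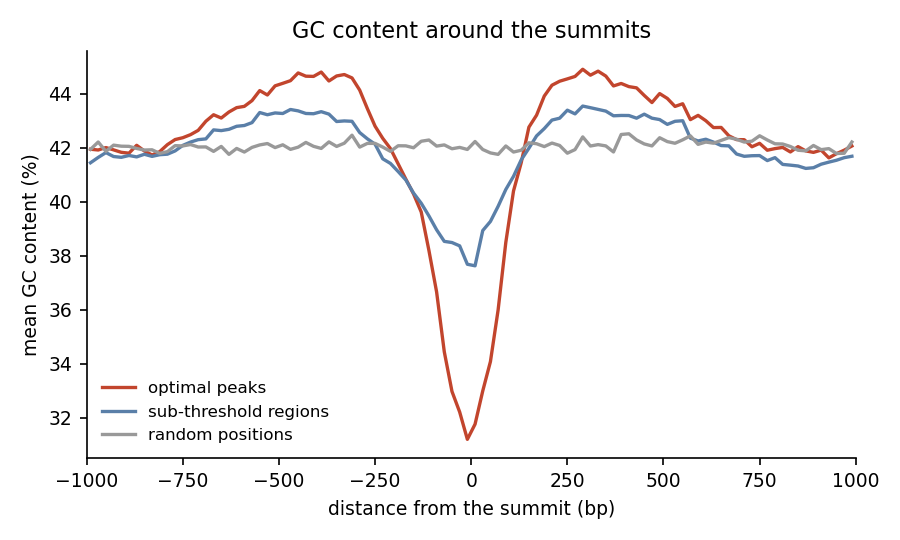
Mean GC content (y axis, %, axis not starting at 0) against distance from the summit (x axis, bp) in bins of 20 bp for optimal peaks, sub-threshold regions and random positions. The optimal peaks show a narrow trough, with a mean of 34.1% within 100 bp against 38.8% for sub-threshold regions and 42.0% for random positions.

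The TATA box, the TA repeat and the homeodomain site, all rich in A and T, were more frequent at optimal summits. Of 27 fixed motifs, 6 were more frequent at optimal summits, namely the TATA box (16.9% against 11.8%, odds ratio 1.51), Ohler motif 6 (9.27% against 6.52%), DRE (2.02% against 1.45%), Ohler motif 7 (8.88% against 6.95%), the TA repeat and the homeodomain site. Another 7 were less frequent, including the CA repeat (3.31% against 5.78%, odds ratio 0.558) and the CTCF core (4.83% against 6.66%, odds ratio 0.711), with the AP-1, Pho, E2F, Myb and initiator sites. The TATA box had an adjusted p of 1.05e-24 and the CA repeat one of 3.43e-16 in Fisher's exact test. Matching sub-threshold regions on GC content and promoter class left 3 higher (GAGA element, Ohler motif 7 and the CAGCTG E-box) and 2 lower (CA repeat and TCF site), and the TATA box odds ratio became 0.999. Neither the GAGA element nor the CAGCTG E-box was called by default, and in other settings both were called lower, with odds ratios of 0.780 for the GAGA element at promoter peaks and 0.768 for the CAGCTG E-box at the stricter threshold. DRE, the TA repeat and the homeodomain site fell below 1 with this matching, at 0.895, 0.880 and 0.932, without passing the test. Only Ohler motif 7 and the CA repeat were called in both versions. The excess of Ohler motif 7 was found at promoter peaks (14.6% against 10.4%), while at the 4269 peaks more than 500 bp from every start site its share was 4.94% against 5.75% (odds ratio 0.852, not passed). Its call also ended with 50 bp on either side. The AP-1, E2F and initiator calls ended with either replicate alone (odds ratios from 0.836 to 0.943) and the TA repeat call without replicate 1 (1.16), while the DRE call passed under 3 of 9 other settings.

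In an open search over 2080 hexamers, 36 were enriched on 2L, 2R and X, and 25 of these passed again on 3L, 3R and 4, of which 21 held only A and T. TTAAAA led, in 54.9% of optimal windows against 39.0% on the arms held back (odds ratio 1.90, Fisher's exact test, p = 8.23e-55). Matched on GC content and promoter class, 2 hexamers passed on both sets of arms, led by ACAGTG (14.5% against 9.52%, odds ratio 1.61). Neither held only A and T. By default ACAGTG was enriched on 2L, 2R and X but did not pass on the arms held back (odds ratio 1.47). Without matching, the count passing on both sets was 13 without replicate 1 and 24 without replicate 2.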

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

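Merging of overlapping regions and assignment to the nearest start site only were chosen after the result was seen; all other settings were planned. The replicate overlap (71.8% to 86.0%), the promoter share, the upstream summit offset and the higher signal at promoters kept their direction and passed under every setting run. The X share of 18.8% reversed direction when compared with chromosome length, because the reference share changed from 20.4% to 17.8%. Of the motif counts, 6 higher and 7 lower became 10 and 4 with 250 bp on either side, 3 and 2 with GC and promoter matching, and the higher count 2 at distal peaks alone. The matching changed GC content and promoter class together. Within promoter peaks and within distal peaks the TATA box stayed higher (1.75 and 1.41), so promoter class alone does not account for its loss, while DRE was not called in either (1.01 and 0.782). Distal in the motif settings means more than 500 bp from every start site. With each replicate alone the motif counts were 5 to 6 higher and 4 to 6 lower. Direction and call were kept by 183 of 243 single motif odds ratios, 116 of 135 core element ratios and 278 of 306 list differences, where values called in neither setting count as kept. Among motifs called by default or in the other setting, 17 ratios crossed 1. With 250 bp on either side these were the GAGA element (1.21), the long GAGA repeat (1.42), Motif 1 (1.502), the CAGCTG E-box (1.14), the TA repeat (0.938), the E2F site (1.12) and the Myb site (1.01). With matching they were the GAGA element (1.205), DRE (0.895), the CAGCTG E-box (1.22), the TATA box (0.999), the CTCF core (1.01), the TA repeat (0.880), the homeodomain site (0.932) and the E2F site (1.17), and at distal peaks DRE (0.782) and Ohler motif 7 (0.852). The E2F site, the GAGA element, the long GAGA repeat, Motif 1 and the CAGCTG E-box were called lower in some settings and higher in others, and of these only the E2F site was called by default. The GAGA element at core promoters crossed 1 with the 200 bp definition of bound (0.910). The number of hexamers that passed went from 25 to 41 at the stricter threshold and to 13 to 24 with each replicate alone. With matching 2 passed, neither of them made only of A and T. Core promoter elements fell from 11 to 7 at the stricter threshold and to 7 with GC matching, where the background was also smaller and, of the 4 lost, only the GAGA element moved close to 1 (1.03). Gene lists with a higher share numbered 5 with the 200 bp definition of bound, 1 with 1000 bp and 1 with clustered genes thinned, which also left 2 lower lists. Restricting the background to genes with any pooled region left 1 lower list, the tRNA genes (25 of 164, a difference of -18.8 percentage points from other genes, reversed in direction), since it left 7 chemosensory, 8 cuticle and 0 histone genes to test. Without replicate 1 translation factor and insulator lists were called higher, and the long non-coding and microRNA lists were not called. What caused the other moves was not tested. Depth is unknown and sets no stated limit.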

Other observations

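The test that compares ribosomal protein genes with oxidative phosphorylation and proteasome genes, the genes ranked by number of regions and the mitochondrial and chromosome 4 values were chosen after the result was seen. Counted after merging of overlaps, kirre, which encodes an adhesion protein of muscle founder cells, held the most separate optimal regions in its span, 29 over 394 kb (7.36 per 100 kb), followed by Ten-a with 17 (5.83 per 100 kb). At higher density, shn, a zinc-finger gene of Dpp signalling, had 16 regions over 58.3 kb (27.4 per 100 kb), and CHES-1-like, a forkhead gene, had 12 (44.4 per 100 kb). The arms together had 4.57 per 100 kb. Mnt (11 regions), tna (11), pnt (12), ush (12), mam (12) and rdx (12) were further examples, each above 17 per 100 kb. No test was made of these densities.

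On chromosome 4, the 13 optimal peaks included Sox102F (signal 1085, 281 bp from a start site), gw (558) and RpS3A (186). On the mitochondrial chromosome of dm6, replicate 1 alone listed 2 summits in a region from 1376 to 2635, and its signal of 3498 was the highest of that replicate. The dm3 lists of replicate 1 held mitochondrial regions with signals of 101 and 95.7, those of replicate 2 had 73.1 and 70.5, and the optimal dm3 list kept 2. These values are given without explanation.

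Ribosomal protein promoters were bound in 64.8% of cases, and binding might follow abundant transcription of genes used in all cells, promoters shared with neighbours, or a larger number of annotated start sites. Oxidative phosphorylation and proteasome genes were bound in 24.8% (27 of 109), below the ribosomal protein genes by Fisher's exact test (p = 1.45e-08), but no expression values were used here to show how abundantly either group is transcribed, so abundance stays open. Among genes with no other gene's start site within 1 kb, 7 of 19 ribosomal protein genes were bound against 12.1% of others (odds ratio 4.24, Fisher's exact test, p = 0.00512), and with the 5'-most start site alone the odds ratio was 8.30, so neither of the other explanations is the whole cause. A preference of the tagged protein, or of the immunoprecipitation, for this promoter class stays open too, since the control was not analysed here.

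The AT-rich trough at optimal summits might come from the mix of annotation classes or from regional base composition or GC bias of the fragments. Within introns alone the median GC content was lower by a difference of -4.48 percentage points (permutation p = 1e-04, the smallest possible), and it was lower at promoters and in intergenic sequence as well, so the mix is not the whole cause. The difference 400 to 600 bp away was -19.7% of that within 100 bp, that is, of the opposite sign, which argues against a regional cause and against a bias as wide as the longer fragments. How the authors' caller places a summit within a region, and a bias on the scale of the shortest fragments, stay open.

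The core promoter elements that were higher at bound promoters could reflect base composition of the promoters, or the ribosomal protein and mitochondrial ribosomal protein genes alone. With unbound promoters matched on GC content, 5 of the 7 elements still passed as higher, and without the ribosomal protein and mitochondrial ribosomal protein genes 7 of 7 were. Neither explanation is then the whole cause. DRE contains CGATA, so those elements are not counted independently. The unbound promoters include those with no pooled region, and a core promoter comparison limited to promoters with a sub-threshold region was not made. Whether the elements mark promoters with any pooled region therefore stays open. At the summits themselves the TATA box was higher and lost its excess with matching on GC content and promoter class, while in the core promoter window it was lower with and without matching. Whether these elements are also enriched under other tagged proteins was not analysed here.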
